A study of Homo sapiens with 6 samples.

How the data were processed

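The series holds 6 RNA samples of KGN cells, 3 labelled as IAA treatment and 3 as control, each with a replicate number. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected by its poly(A) tail, libraries kept the strand through dUTP, and fragments were read in pairs. Per the submitters' processing notes the genome build was hg38. The aligner, the counting program, the annotation and the authors' test program are not given in the sources used here.

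The deposited table lists 565 genes, per the file headers with a value for each of the 6 samples and the authors' log2 fold change, log2 CPM, p-value and FDR. The title line inside the table names another comparison, while its columns carry the names of these samples and its genes are human; the columns were matched to the samples by name. The authors had selected the genes: the smallest absolute log2 fold change in the deposited table is 1.00 and the largest FDR 0.0435. The ratio of the deposited FDR to the p-value at the first rank corresponds to 12217 tested genes, so the listed genes are 4.62% of those. The lowest-ranked listed gene stood at rank 7131, within the first 58.4% of the tested genes. No column of per-sample values was left unused.

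The deposited sample columns were taken as FPKM per kilobase of coding sequence by the authors. This follows from the values: the authors' CPM divided by the mean sample value gave the longest GENCODE 29 coding length, with a median log2 offset of 0.02 over 211 genes with every value above 5, 74.4% of them within 0.1. Coding lengths were found for 535 of the 565 genes (94.7%), matched by symbol. The deposited log2 fold changes lay below the log2 ratio of mean FPKM by a median of 0.11 (offset -0.11), a shift from the authors' own scaling. Read totals per sample were recovered from the values of low genes, which fall on whole multiples of 1 read; with 71 to 87 genes per sample, 76.2% to 89.0% of the products of value, length and total lay within 0.2 of a whole number. They range from 11750000 to 20590000 reads. Counts as such were not used here.

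Tests were run in R 4.3.3 with limma 3.58.1, with a trend and robust variance estimates, on log2(FPKM + 1), keeping genes with at least 1 FPKM in at least 3 samples (500 of 565). The contrast was IAA against control with all 6 samples and no covariate, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Of 32 gene lists with 844 genes, those with at least 5 tested members were compared with the other listed genes by camera with a correlation preset to 0.01; 2 lists qualified. Since the background is the authors' selection, no enrichment against the transcriptome was computed. For 12 of the lists no member was in the table, and these were not analysed here: aryl hydrocarbon receptor targets, steroid synthesis, glycolysis, nuclear and mitochondrial oxidative phosphorylation genes, antioxidant, heat shock, NF-kB, autophagy, insulin signalling, ribosomal protein and epithelial marker genes.

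The design had foreseen a count test for counts and this test for FPKM, and the latter was used. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 13 genes set in advance where listed, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with separated groups and a mean of at least 2 FPKM in the higher group, and up to 4 members with the smallest p of each list with a member past the threshold. The result of 1 gene that the rule names is not reported here. Genes with near-identical copies are uncertain, because the authors' counting could split their reads: FAM72B, FAM72C and FAM72D, H4C1, and the genes whose symbols end in -2. The actin genes ACTA2 and ACTG2 are related but separate genes, and whether they shared reads was not tested.

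On data simulated for the comparison of IAA with control (477 genes past the filter, 185 of them changed, a coefficient of variation of 7%), the test called 39.6% of genes changed 1.2-fold, 97.7% at 1.5-fold, 97.9% at 2-fold, 100% at 3-fold and 1.7% of unchanged genes. The simulated genes were mostly unchanged (292), while the real ones were all chosen as changed, so these rates do not carry over directly. The median spread beyond counting was 0% to 3.1% in IAA and 5.04% to 11.9% in control samples, by read class. Replicates were compared before averaging: the variance between samples of a group was 2.53 to 7.20 times the counting variance, so no 2 samples were treated as one. Alternatives covered the filter, the pseudocount, the scaling, the replicate number as a block, each sample left out, an estimated correlation between genes and the rotation test fry. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining computations. Transcript lengths and GC content came from GENCODE 29 on GRCh38.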

Results

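Polyadenylated RNA of KGN cells, a line derived from a human granulosa cell tumour and used as a model of the hormone-producing cells of the ovarian follicle, was sequenced from 3 samples treated with IAA and 3 control samples. The title of the series spells IAA out as indole-3-acetic acid, a breakdown product of tryptophan made by gut bacteria, and places the question in granulosa cell dysfunction under metabolic stress in polycystic ovary syndrome. The labels used here give neither the dose nor the duration of the treatment, nor whether a metabolic stress was applied to either group. The values analysed were FPKM of 565 genes that the authors had already selected as different between the groups, out of 12217 genes that they tested. The selected genes all had a log2 fold change of at least 1.00 in size. The last-ranked of them, at an FDR of 0.0435, stood at rank 7131 of the tested genes. About 58.4% of the tested genes thus had an FDR no higher than that, so the 565 are not all the genes that differed. Genes outside that selection were not analysed here, so every statement covers the listed genes. The read totals behind the FPKM values, recovered from the steps between low values, were 20590000, 12520000 and 16850000 for IAA samples 1 to 3 and 11750000, 13500000 and 11900000 for control samples 1 to 3. A gene with a coding sequence of 1 kb and a value of 1 FPKM therefore rested on about 12 to 21 reads per sample. Across the listed genes, which are not independent replicates, log2 values correlated with r between 0.984 and 0.994 within groups and between 0.880 and 0.916 across groups.

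The comparison of IAA with control asked which transcripts differ in granulosa-like cells exposed to this metabolite. Transcripts for cell division fell in the IAA samples, among them UBE2C, which loads ubiquitin for the anaphase-promoting complex, and PLK1 and AURKB, kinases of mitosis. The contractile genes TAGLN, ACTA2 and ACTG2 fell as well. Among the genes past the filter on low values, the highest rise belonged to SCD, the desaturase that makes monounsaturated fatty acids, from 172 ± 30.4 to 780 ± 49.7 FPKM (SD, n = 3 per group), a 4.54-fold difference. AMH, the granulosa cell hormone anti-Müllerian hormone, fell. Of the 565 genes in the authors' deposited table, 299 were higher and 266 lower with IAA, with log2 fold changes from -3.64 to 2.19. Of the 500 genes with at least 1 FPKM in at least 3 samples, 258 were higher and 236 lower at an adjusted p under 0.05 (limma on log2(FPKM + 1), Benjamini-Hochberg, two-sided). Because the list had been chosen on these samples, these counts are not independent evidence of a difference. The 3 IAA values all lay above or all below the 3 control values for 491 of the 500 genes, an arrangement that chance gives for 10% of unselected genes.

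Among the genes that rose most, SCD lies on chromosome 10 (GRCh38, 100347232 to 100364826, plus strand) and changed by 2.19 ± 0.11 (log2 fold change ± SE, limma adjusted p = 4.95e-08). TCF4, a basic helix-loop-helix transcription factor, rose from 7.53 ± 0.70 to 22.8 ± 1.36 FPKM. KLHL24, which encodes a kelch-like protein, rose 3.77-fold, and CREBRF, a regulator of CREB3 proteins, rose 3.75-fold. PSD3, SLITRK4, TENT5A and PDE5A rose between 2.94-fold and 3.25-fold. ZMAT3, an RNA-binding p53 target, rose from 2.72 ± 0.50 to 8.62 ± 1.55 FPKM. YPEL2 rose 4.39-fold with a wide spread, from 1.2 ± 0.64 to 5.25 ± 1.96 FPKM. Over the higher genes of the table, control sample 2 lay above the other control samples by a median of 0.14 on the log2 scale.

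Among the genes that fell most, ACTG2, the enteric smooth muscle actin, went from 6.03 ± 0.19 to 0.49 ± 0.19 FPKM, 12.3-fold lower. TAGLN, an actin-binding protein of contractile cells on chromosome 11 (GRCh38, 117199293 to 117207465, plus strand), fell from 199 ± 11.7 to 54.4 ± 2.63 FPKM. PLK1 on chromosome 16 (GRCh38, 23678888 to 23690367, plus strand) fell from 164 ± 5.75 to 55.2 ± 0.58 FPKM, a log2 fold change of -1.55 ± 0.05 (limma adjusted p = 4.97e-09). UBE2C was 3.41-fold and AURKB 3.13-fold lower. PKMYT1, an inhibitory kinase of CDK1, TACC3, a protein of the mitotic spindle, and PIF1, a DNA helicase, were 2.94-fold, 2.87-fold and 3.28-fold lower. The transcription factor genes MXD3 and BATF3 were 2.98-fold and 3.51-fold lower.

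**Figure D1:**
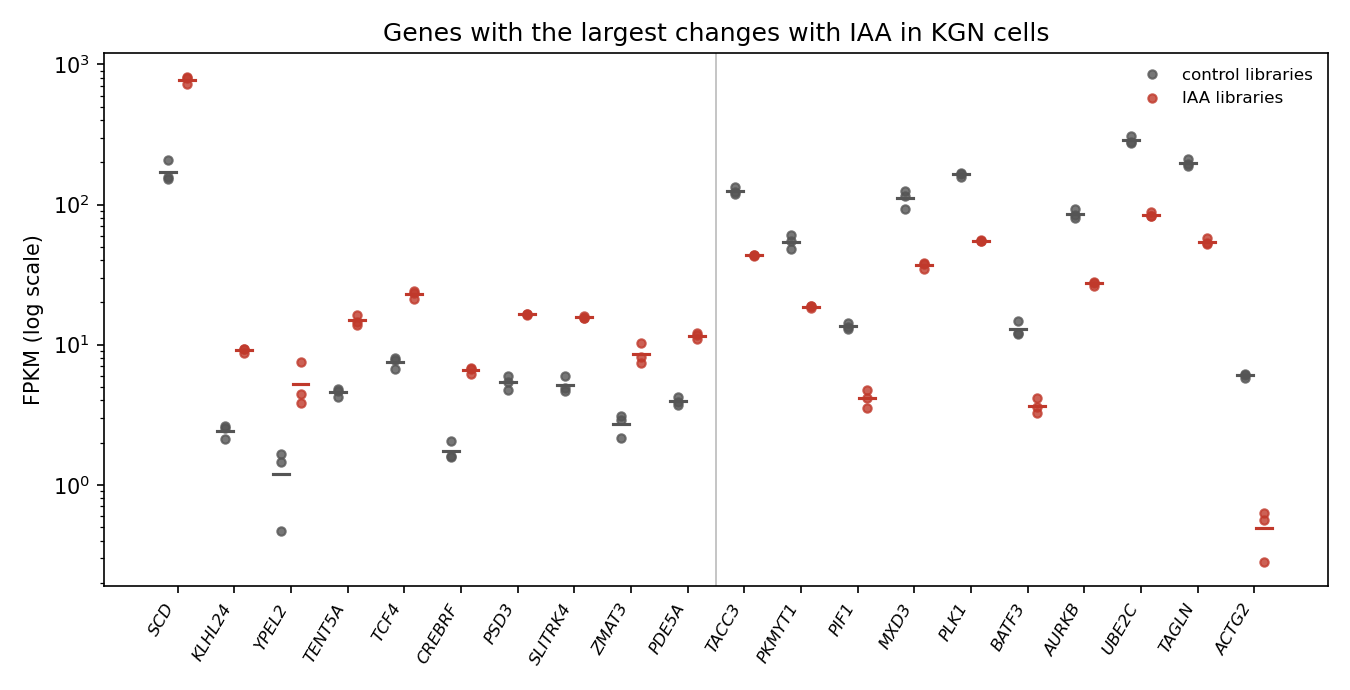
FPKM on a log axis for the 10 genes with the largest positive and the 10 with the largest negative log2 fold changes under the naming rule, with points for the 3 control (grey) and 3 IAA (red) samples and a line at each group mean. The 3 IAA values lie on one side of the 3 control values for each of the 20 genes, and SCD reaches a mean of 780 FPKM with IAA against 172 FPKM in control.

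Both cell cycle lists moved one way. The authors' table held 12 of 30 S phase genes and 21 of 32 genes of G2 and mitosis, and each of these 33 genes fell, also when adjusted over the list alone. In S phase, the nucleotide synthesis genes RRM2 and TYMS fell from 189 ± 8.23 to 79.7 ± 1.34 FPKM and from 261 ± 5.34 to 121 ± 4.87 FPKM, and the replication genes GINS2 and MCM7 were 2.70-fold and 2.06-fold lower. In mitosis, CDC20, an activator of the anaphase-promoting complex, fell from 217 ± 4.08 to 76.4 ± 1.24 FPKM. The median log2 fold changes were -1.08 for S phase and -1.11 for G2 and mitosis, and under quantile normalization MCM5, FEN1 and KIF20A turned to the opposite direction. That normalization took the median of the 33 genes to -0.29 and left 8 of the 12 and 14 of the 21 genes called in the same direction. Folds came near 0 for some of the others, with CDK1 at -0.03 and MCM7 at -0.08 on the log2 scale. It gives every sample the same distribution of values and was computed over genes all chosen as changed, so it had no unchanged genes to scale on. Against the other listed genes the lists were lower with adjusted p = 0.000111 and 1.69e-07 (limma camera, 2 lists tested). With an estimated correlation between genes the adjusted p = 0.0641 for S phase, which ended that call, and adjusted p = 0.00936 for G2 and mitosis. The authors had chosen every listed gene as changed at least 2-fold between these same samples. The falls of single members and the camera calls therefore followed largely from that choice and are not independent evidence. Control sample 2 stood nearer to the IAA samples than the other control samples did, by a median log2 difference of -0.05 over these cell cycle genes.

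**Figure D2:**
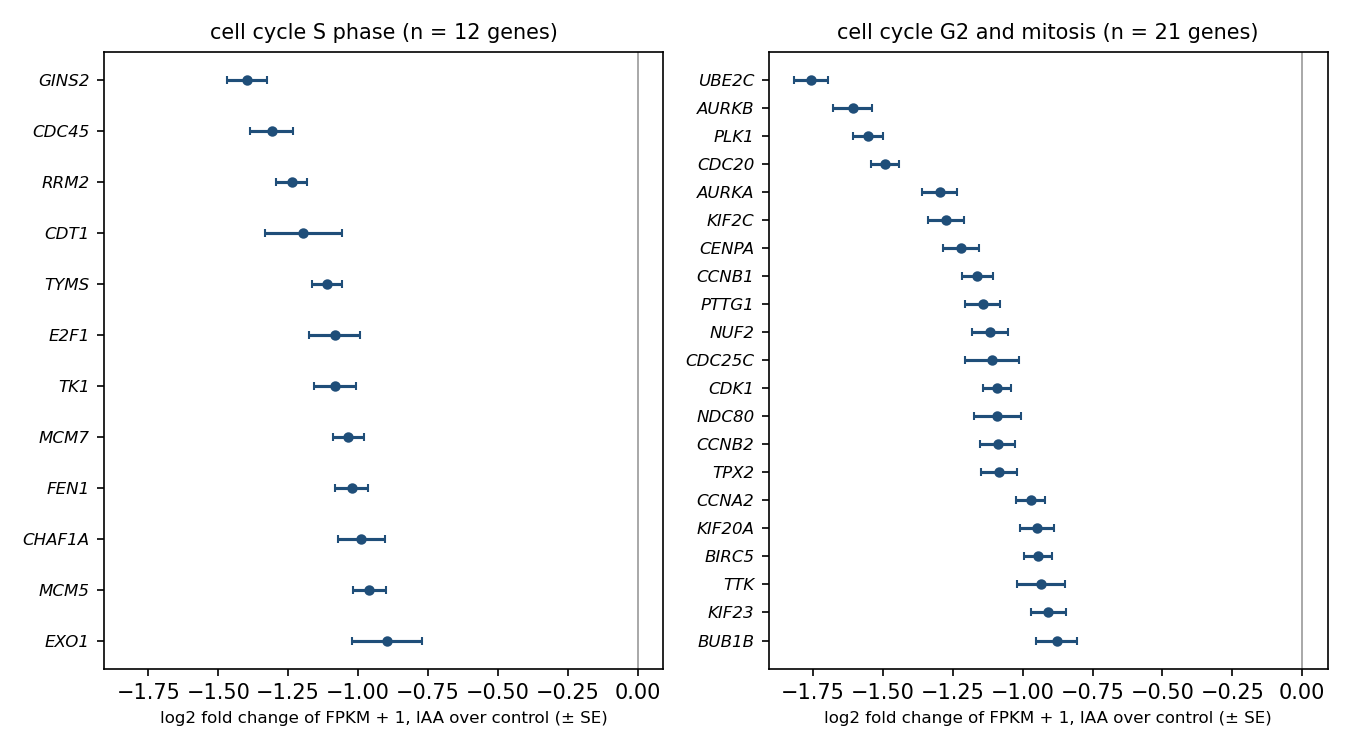
Log2 fold change of FPKM + 1, IAA over control, with its standard error, for the 12 S phase genes and the 21 genes of G2 and mitosis among the listed genes. The 33 points lie below 0, with UBE2C at -1.76 the lowest and BUB1B at -0.88 the highest; under quantile normalization MCM5, FEN1 and KIF20A turn to the opposite direction.

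Of the genes of granulosa cell identity, AMH on chromosome 19 (GRCh38, 2249322 to 2252073, plus strand) fell from 10.9 ± 1.95 to 5.53 ± 0.57 FPKM (limma adjusted p = 8.46e-05). Of 13 genes of aryl hydrocarbon receptor signalling, steroid synthesis and granulosa identity that were to be named whatever their result, AMH was the 1 in the table, and the other 12 were not analysed here. TDO2, which opens the tryptophan ring, rose from 1.47 ± 0.31 to 3.60 ± 0.46 FPKM.

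Lipid and stress genes changed singly or in small numbers. LPIN1, a phosphatidate phosphatase, rose 2.55-fold. ANGPTL4, a secreted inhibitor of lipoprotein lipase, and UCP2, a mitochondrial carrier, were 4.00-fold and 2.07-fold lower. The 2 other listed genes of fatty acid oxidation, PPARGC1A and PDK4, named after their values were seen, were higher in the authors' deposited table but too low to be tested here, with 0.40 ± 0.09 against 0.09 ± 0.08 FPKM and 1.09 ± 0.10 against 0.42 ± 0.37 FPKM. The amino acid transporter SLC38A2 rose from 99.0 ± 13 to 252 ± 10.5 FPKM, and ALDH1L2, a mitochondrial folate enzyme, rose 2.36-fold. SDF2L1, a chaperone cofactor of the endoplasmic reticulum, was 2.16-fold lower. The p53 target TP53INP1 rose 2.40-fold beside ZMAT3. Of the 4 listed apoptosis regulators, XIAP, which inhibits caspases, and BCL2L11 and BMF, which promote cell death, rose 2.33-fold, 2.30-fold and 2.68-fold. BIRC5 fell from 227 ± 5.63 to 118 ± 1.35 FPKM, and it already counts among the falling genes of G2 and mitosis above. The calls of BMF and BIRC5 ended under quantile normalization, at log2 fold changes of 0.41 and -0.10. MXI1, a MYC antagonist, rose 2.17-fold, SLC40A1, the cellular iron exporter, rose 2.63-fold, and IFIT2, an interferon-induced gene, rose 3.10-fold.

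Of the 4 listed immediate early genes, NR4A2 rose 3.16-fold and CCN1, FOSL1 and EGR1 fell, CCN1 from 305 ± 5.58 to 151 ± 1.35 FPKM, a call that ended under quantile normalization at a log2 fold change of -0.02. ACTA2, smooth muscle actin, fell from 101 ± 5.83 to 36.1 ± 2.34 FPKM. HMGB2, a chromatin protein, fell from 734 ± 37.6 to 330 ± 6.72 FPKM, and the nuclear lamina gene LMNB1 was 1.92-fold lower but turned to the opposite direction under quantile normalization. Among markers of other cell types, the stromal gene PDGFRA rose 2.65-fold while ACTA2, on the same list, fell, and the endothelial gene KDR rose from 0.68 ± 0.18 to 1.55 ± 0.14 FPKM. The call of KDR ended under quantile normalization and under median centring, at log2 fold changes of 0.24 and 0.22 in place of 0.61. H4C1, a histone gene whose transcripts usually lack a poly(A) tail, fell from 9.29 ± 1.33 to 3.48 ± 1.33 FPKM. It was the 1 gene in the authors' selection out of 38 such histone genes, set in advance as a sign of library quality, and 1 gene does not settle whether quality differed.

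Of the 500 tested genes, 256 passed the test with at least a 2-fold change on the log2(FPKM + 1) scale, which understates the change of low genes, 137 of them higher and 119 lower. That split depended on the scaling: it was 8 higher and 229 lower after median centring and 58 and 98 after quantile normalization. Both were computed over genes all chosen as changed. With the IAA values on the log2(FPKM + 1) scale lowered by 0.11, the offset of the authors' scaling, the split was 82 and 182. It is not the authors' own result: by selection, their log2 fold changes are all at least 1.00 in size. Of the 565 listed genes, they had 299 higher and 266 lower. Of the 52 named genes, 30 had a log2 fold change smaller by over 1.5 times after quantile normalization and 10 after median centring. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.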

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

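The shift to the authors' scaling, the lists under other scalings and fry with the block were chosen after seeing the data. With at least 5 FPKM in at least 3 samples, 343 genes were tested, with 146 higher and 194 lower in place of 258 and 236. Fewer low genes entered, and more of the higher than of the lower calls were lost, so lower genes outnumbered higher ones. The count of genes changed at least 2-fold was 414 with a pseudocount of 0.1, which shrinks low values less, and 156 after quantile normalization, where the cause was not tested. With an estimated correlation between genes, 1 list was called lower in place of 2. LMNB1 reversed to 0.11 on the log2 scale after quantile normalization (limma adjusted p = 0.137; the cause was not tested). Of 666 values of the named genes under alternatives, 659 kept their direction and side of the threshold, 6 lost the call in the same direction (BIRC5, BMF, MCM7, CCN1 and KDR after quantile normalization, KDR after median centring), and the 1 for LMNB1 reversed. Leaving out each sample in turn gave 258 to 258 genes higher, 233 to 236 lower and 242 to 289 changed at least 2-fold; the 289 came without control sample 2. Because the authors chose the genes on all 6 samples as changed at least 2-fold, calls that stayed the same under the alternatives are no independent sign of robustness. No list was called higher by camera or fry in any setting run, and 0 of the 2 were higher at an unadjusted p under 0.05. With the replicate number as a replicate block, 258 genes were higher, 238 lower and 259 changed at least 2-fold, with 0 lists higher and 2 lower. Deviations of same-numbered samples correlated at 0.05, 0.40 and 0.47, and those of other-numbered samples between -0.476 and 0.235. IAA samples 2 and 3 correlated best with the control sample of their own number, and IAA sample 1 with control sample 2. The main test had been planned without a block, since the labels name no batch, and a batch shared by replicate number stays possible. The alternatives planned for counts were not run, because the values are FPKM. Depth limits the genes below 1 FPKM, which rest on few reads.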

Other observations

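Gene families outside the fixed lists were grouped by symbol or annotation after the values were seen, and their genes were chosen in the same way. Of the 12 listed genes whose annotation names a KRAB domain, which recruits repressors to zinc finger proteins, 11 were higher with IAA in the authors' deposited table, and the 9 tested ones rose in the limma test. ZNF436 rose from 6.26 ± 1.19 to 17.3 ± 1.36 FPKM and RBAK from 1.82 ± 0.02 to 4.47 ± 0.38 FPKM (SD, n = 3). Of the 14 genes with SLC symbols 12 were higher, among them the zinc transporter SLC39A10, from 9.0 ± 0.66 to 22.5 ± 0.82 FPKM, and the taurine transporter SLC6A6, from 13.5 ± 2.44 to 30.8 ± 0.13 FPKM, while the folate carrier SLC19A1 and the mitochondrial carrier SLC25A10 fell. SLCO4A1 and UCP2, carriers under other symbols and outside that tally, fell too, so the tally says nothing of solute carriers as a class. Against the direction of the other listed genes the share of KRAB genes gave Fisher's exact p = 0.00681 (adjusted 0.0306) over 9 families, 2 of which overlap. The 5 CDCA genes of cell division fell, CDCA3 from 103 ± 3.86 to 37.0 ± 3.14 FPKM, with an adjusted p of 0.051 by Fisher's exact test, which missed the threshold. No tested KRAB, SLC or CDCA gene changed direction under quantile normalization; the other scalings move every gene by the same amount, too little to turn these.

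The 6 tested genes that missed the limma threshold were PPP2R3B-2, SERF1B, GTPBP6-2, BOLA2B, LOC102724594 and SLX1A, named after their values were seen. Their values were uneven within groups: BOLA2B stood at 3.20, 2.17 and 76.16 FPKM in the IAA samples and at 139.42, 3.16 and 127.95 FPKM in the control samples.

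The tests in the paragraphs that follow were all chosen after the results were seen, and so were their thresholds. The 3 against 3 samples make 10 splits, so the share of splits with a result as large is never under 0.1. For the genes called, the real split gave 494 and the highest other split 2, with 1 of 10 splits as large. For genes changed at least 2-fold, it gave 256 against 2, again 1 of 10. The genes had been chosen for differing between these same IAA and control samples. Both outcomes therefore followed largely from that choice, and they decide nothing about chance. Both cell cycle lists were called in 10 of 10 splits, the highest other split calling 2, so the camera call does not set the real grouping apart; with 3 samples a side, each other split still holds more IAA samples on one side.

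The first pattern is the fall of the 33 listed cell cycle genes. The tables argue against library depth: the deepest IAA library held 1.65 times the reads of the shallowest, more than the 1.34-fold gap between group means, yet the median log2 ratio of these genes between them was 0.00284, against -1.09 between IAA and control. Of 10000 sets of other listed genes matched on transcript length and coding GC content, 0% were all lower. The median share of lower genes in a set was 60.6%, so an all-lower set was unlikely from the start. The highest share was 84.8%, so the 33 genes were lower more often than any matched set. The other listed genes still included genes of cell division outside the lists, such as TACC3 and CDCA3. What part of the fall goes with length and GC content therefore cannot be read from these sets. An effect of the treatment on proliferation may account for the fall, as a hypothesis that was not tested, and differences in culture density stay open as untested too. The scaling between libraries stays open too, since genes outside the selection were not analysed here. The median log2 fold change of the 33 genes was -0.29 after quantile normalization and -1.48 after median centring. With the shift to the authors' scaling it was -1.20, and the authors' own log2 fold changes were below 0 for all 33. Quantile normalization and median centring were computed over genes all chosen as changed. They had no unchanged genes to scale on, so they decide little here.

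The second pattern is that higher genes had longer transcripts, with a median of 5794 bp against 2131 bp for lower genes, and longer 3' UTRs, 3090 bp against 395 bp (288 and 247 genes, permutation p = 5.0e-05 for each, the smallest that 20000 permutations give). Without the cell cycle lists the ratio of median transcript lengths was 2.76, so these lists are not the whole of it. Coding GC content differed as well, with a median of 45.0% in higher against 57.0% in lower genes (permutation p = 5.0e-05). Without the cell cycle lists it was 45.0% against 58.0% (permutation p = 5.0e-05). A library trait tied to length, such as RNA integrity, could contribute: control sample 2 deviated from the other control samples along transcript length with Spearman's rho 0.436 across genes, which are not independent replicates, while rho was -0.11, -0.02 and 0.11 for IAA samples 1 to 3. Within the higher and the lower genes alone rho was 0.11 and 0.26 for control sample 2, and -0.07 and -0.32 for control sample 1, whose deviation is partly the mirror of that of control sample 2 because each was taken against the others. Along coding GC content rho was -0.05, -0.197 and 0.294 for control samples 1 to 3, and 0.155, 0.0251 and -0.167 for IAA samples 1 to 3. Control sample 2 was also shifted towards the IAA samples, by a median of 0.14 on the log2 scale for higher genes. Because the table holds only genes chosen for their change, a library trait tied to length or GC content and the treatment cannot be told apart here.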
